A study of Mus musculus with 12 samples.

How the data were processed

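Whole mouse embryos at embryonic day 9.5, all labelled female, were measured on 12 one-colour Agilent arrays, 4 for each of 3 genotypes of the whirligig allele of Chd7: wild type, heterozygous and homozygous. The labels call the samples of a genotype biological replicates, and embryos had been dissected away from their yolk sacs, per the labels' protocols. Replicates are numbered in accession order, so a number only names an array. The spots were quantified with Agilent Feature Extraction 10.7.3.1 in 1 channel (Cy3), per the file headers and the submitters' processing notes, which also name limma with no version. The intensity values used are the deposited processed signal of each spot, which that software had corrected for background and spatial trends within the array, per the file headers, and which had not been scaled between arrays. The deposited value table of the series held the same intensity values as the scanner files, with a largest relative difference of 0 on each array, so its scale is linear and it was not centred.

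From these intensities, log2 of the processed signal minus the array's own 75th percentile was computed. Control spots (1377) were left out, as were spots marked as non-uniform or as population outliers, between 171 and 386 per array, and no spot was saturated. Spots of 1 probe were averaged on the log2 scale. Of 39429 probes, 26055 were named through their transcript accession, without version, in a RefSeq gene table of assembly GRCm38.p6, giving 19751 genes, and 13374 probes kept the identifier of the file. That table was used for names and for which genes neighbour each other, and no coordinate is given because the array design was annotated on another build. Of each gene's probes, the one with the highest mean over the 12 arrays was used. A probe was tested when it was well above background on all arrays of at least 1 genotype, which left 22563 genes or identifiers.

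One linear model with a mean for each genotype was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), followed by 3 comparisons and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05 and, for a second count, a log2 fold change of at least 1. The group means, SDs and log2 fold changes below are on this scaled log2 signal, with n = 4 arrays per genotype, and errors of fold changes are standard errors of the fit. For a probe that was not well above background on any array of the dimmer group, the fold is a bound: the mean of the brighter group against the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own. The 28 gene lists, fixed before the data were examined, were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the lists of a comparison, again with an estimated correlation, and with fry. In a simulation of homozygous minus wild type with the measured means and spreads (22563 genes, 10 draws), 74.6% of genes changed by 1 on the log2 scale were recovered, 87.2% at 1.5, 95.4% at 2 and 97.8% at 3, and 4.82% of the calls were false. Genes were simulated independently of each other, so these shares take no account of correlation between genes.

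The genes named were chosen by a rule fixed before the data were examined. They are the 8 largest changes in each direction among genes past the threshold whose arrays did not overlap between the groups and whose name is in the gene table. For each list, the 2 members with the smallest p that passed are also named, or, where a list shifted and no member passed, its 2 members with the smallest p as values only. The genes of the sex check complete the rule, and members named beyond it are marked where they appear. The alternatives were normexp background correction, quantile normalization, the value table, 2 other filters on dim probes, every probe on its own, slide or title number as a block, only the genotypes compared, another variance model, array weights and leaving out each array. Normexp had been planned on the mean spot signal and was run on the median spot signal, the column used here, with an offset of 50. This offset is added before the log2 and shrinks fold changes, most for dim probes. The position of an array on its slide as a block was added after seeing the data. Figures were drawn with matplotlib 3.10.9. Precision is limited by the number of arrays.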

Results

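Expression was measured in 12 whole female mouse embryos at embryonic day 9.5, the time at which neural crest cells migrate, to ask which genes depend on functional Chd7, a chromatin remodeller mutated in CHARGE syndrome. The whirligig allele was present on 0, 1 or 2 copies in 4 wild-type, 4 heterozygous and 4 homozygous embryos. Between 69.2% and 75.7% of probes were well above background on each array, and the 75th percentile of the processed signal lay between 1095 and 1721. The slope of the spike-in controls was inside the software's range on wild-type replicate 2 alone (0.91), and was 0.82 to 0.89 on the other arrays. The arrays lay on 3 slides of 4 arrays, each with all 3 genotypes. Position on the slide was not balanced, since position 1 held 3 arrays, all of them wild type. The median CV of replicate spots was highest on these arrays, at 7.65%, 7.45% and 7.07%, against 2.89% to 6.73% on the others. Correlations between arrays over all tested genes were 0.986 to 0.995 within a genotype and 0.983 to 0.994 between genotypes.

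No probe could be tied to Chd7 through the gene table, so the level of the mutated gene is not analysed here and did not serve as a check of the labels. Xist, the RNA of the inactive X chromosome, was well above background on 12 of 12 arrays. The Y-linked genes Eif2s3y, Kdm5d and Uty were not well above background on any array, and Ddx3y was on 1, wild-type replicate 1.

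In homozygous embryos, lists of neurogenesis, pharyngeal arch, somite and Hox genes lay lower than in wild type at a preset inter-gene correlation, and no list shifted with an estimated one. With fry, the pharyngeal arch list alone passed (adjusted p = 0.00779). Single genes of axon guidance and skeletal muscle fell, among them Sema3d, Epha3 and Myog, while Sox10 and Tfap2c, of the neural crest list, rose. With limma, 305 of 22563 genes passed the threshold, 110 higher and 195 lower in homozygotes, and 132 of them changed at least 2-fold (37 higher, 95 lower). Of the 305, 265 carried a gene symbol. The arrays of the genotypes did not overlap for 304 of the 305, which choosing genes by a small p favours. They did not overlap for 3176 of all 22563 tested, where chance gives 2.86% of genes. Without a threshold on the adjusted value, 3828 genes had p under 0.05, where chance gives 1128. Within each of the 3 slides the median signed change of the called genes was 0.98, 0.85 and 0.95 on the log2 scale, from genes chosen on the same arrays, and 302 genes were called with slide as a block. Of the 38 genes past the threshold that the naming rule took, 22 kept the call with each of 12 arrays left out in turn. The call was lost without 8 of the arrays in turn for Tff1, Neurod4 and Mrc1, without 7 for Unc5c, Cdx1 and Hhip, 6 for Extl1, 5 for Casp12 and Isl1, 4 for Efcab6, Pkp1, Tecrl and Pou4f1, 3 for Slit2, 2 for Sox10 and 1 for Prrx1. Of the 38, 17 lost it with normexp background correction: the 8 largest increases, Mrc1, Sema3d, Myot, Sln, Neurod4, Cox8b, Cdh7, Isl1 and Cdx1. Slide as a block ended 4 calls (Tff1, Mrc1, Neurod4 and Unc5c), and array position as a block 35, all but Casp12, Myot and Cdh7. Title number as a fixed block ended 33, all but Rasl10a, Acsbg1, Myot, Cdh7 and Sema3d. The count fell to 91 (9 higher, 82 lower) with normexp and to 188 with no filter on dim probes. It fell to 20 with array position as a block and to 19 (4 higher, 15 lower) with title number as a fixed block. It rose to 544 with array weights, 451 in a fit of only the 2 genotypes and 447 without heterozygous replicate 4. It was 149, 136 and 139 without homozygous replicates 1, 2 and 3, and 112 and 114 without wild-type replicates 1 and 4.

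Single genes of axon guidance fell, and their lists did not shift as wholes. Sema3d and Sema3a, class 3 semaphorins that steer axons and neural crest cells, fell by 1.79 ± 0.17 (SE, adjusted p = 0.000617) and by 1.25 ± 0.14 (adjusted p = 0.00167) on the log2 scale. With normexp background correction Sema3d had a log2 fold change of -0.92 (adjusted p = 0.131). A second Sema3a probe had a log2 fold change of -0.75. Of 30 measured semaphorins and receptors 3 fell and none rose, adjusted over the list alone 3 fell and 3 rose, and 19 of the 30 were higher in value. The third member that fell, Sema3c, had a log2 fold change of -1.04 ± 0.14 and is named beyond the rule, after its value was seen. Of 20 ephrins and Eph receptors 2 fell, Epha3 by 2.29 ± 0.36 (adjusted p = 0.0113) and Epha7 by 0.99 ± 0.12 (adjusted p = 0.00167), with -1.32 and -0.38 on other Epha7 probes. Adjusted over the list alone, 2 fell and 1 rose. Of 23 genes of Slit, netrin and related guidance, 3 fell, among them the repellent Slit2, by 0.92 ± 0.16 (adjusted p = 0.0155), and the netrin receptor Unc5c, by 0.79 ± 0.16 (adjusted p = 0.0398), with -1.16 on a second Unc5c probe. Adjusted over the list alone, 4 fell and 2 rose. The 3 lists had adjusted p = 0.763, 0.763 and 0.239 with camera.

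Members of the neural crest specification list moved in both directions. Of 27 measured, 3 rose and 2 fell. Sox10, a transcription factor of migrating neural crest, rose by 1.17 ± 0.20 (adjusted p = 0.0155), and Tfap2c by 1.01 ± 0.15 (adjusted p = 0.00655). Twist1, a mesenchymal transcription factor, fell by 0.93 ± 0.12 (adjusted p = 0.00393). Foxd3 (1.33 ± 0.24) and Zic1 (-1.53 ± 0.26) were the other members past the threshold and are named after their values were seen. Adjusted over the list alone, 3 rose and 3 fell, and the list did not shift as a whole (camera adjusted p = 0.527).

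**Figure D1:**
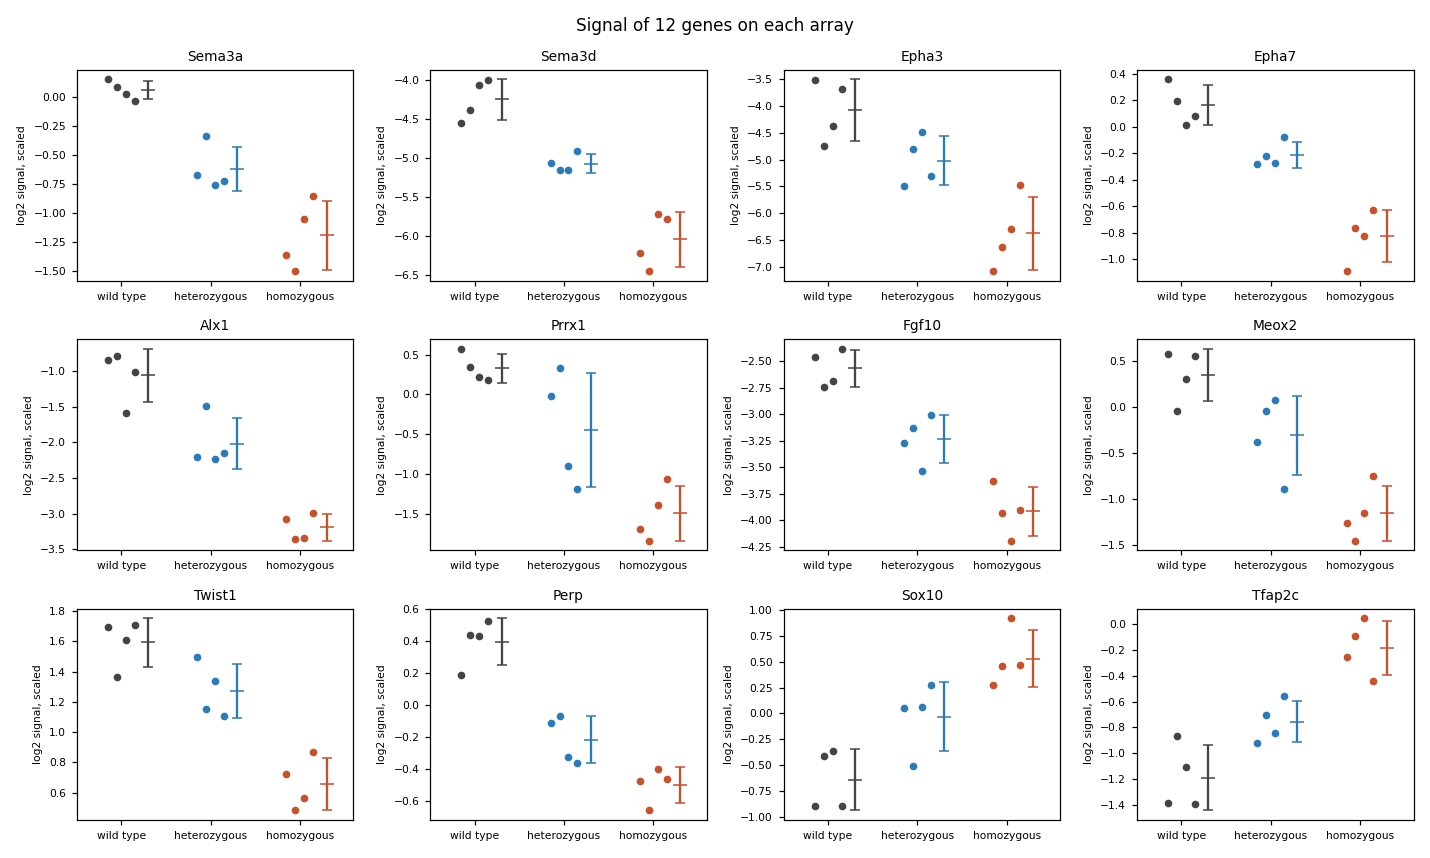
Scaled log2 signal (vertical axes) of 12 genes on each of the 12 arrays, with points for arrays and bars for the mean ± SD of 4 arrays per genotype. Sema3a, Alx1 and Twist1 lie lower, and Sox10 and Tfap2c higher, on the homozygous than on the wild-type arrays without overlap.

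Pharyngeal arch and facial genes were lower as a list at the preset correlation. Alx1, a regulator of facial mesenchyme, fell by 2.13 ± 0.21 (adjusted p = 0.000602) and Prrx1 by 1.82 ± 0.30 (adjusted p = 0.0129; -1.72 on a second probe), and 2 of 32 measured pharyngeal arch and facial genes passed, both lower. Adjusted over the list alone, 11 fell, and 26 were lower in value. The list shifted down (mean log2 fold change -0.45, camera adjusted p = 2.8e-06; adjusted p = 0.161 with an estimated correlation). Of 25 otic and placode genes 1 fell, Fgf10, a growth factor of ear and limb development, by 1.35 ± 0.15 (adjusted p = 0.00128), while adjusted over the list alone 4 fell and 2 rose and the list did not shift (camera adjusted p = 0.239). The otic and placode list passed downwards with array position as a block (mean -0.24). Mesenchyme and matrix genes moved in both directions: of 32, 4 fell and 1 rose, adjusted over the list alone 5 fell and 6 rose, 19 were higher in value, and the list did not shift (camera adjusted p = 0.763). Vcan, a large matrix proteoglycan, fell by 0.75 ± 0.10 (adjusted p = 0.00407), and Has2, which makes hyaluronan, by 0.92 ± 0.13 (adjusted p = 0.00604). Other Vcan probes had log2 fold changes of -0.45 and -0.24.

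Some muscle and somite genes were also lower. Myog, a master regulator of muscle differentiation, had a mean log2 signal of -6.85 ± 0.49 (SD, n = 4) in homozygotes and -3.37 ± 0.44 in wild type (adjusted p = 0.00167), and was well above background on 1 of the homozygous arrays. The sarcomere gene Myot was not well above background on the homozygous arrays and was at least 2.36-fold lower there (adjusted p = 9.71e-05). Sln, a regulator of the calcium pump, was at least 2.43-fold lower (adjusted p = 0.00716). These bounds are on the processed signal, and with normexp the log2 fold changes were smaller and did not pass, at -0.84 for Myot (adjusted p = 0.31) and -0.96 for Sln (adjusted p = 0.197). Tnnc2, a troponin of fast muscle, fell by 1.80 ± 0.24 (adjusted p = 0.0036). Of 18 skeletal muscle genes 4 fell, adjusted over the list alone 5 fell, and 9 were lower and 9 higher in value. The list shifted down (mean log2 fold change -0.52, median -0.05, camera adjusted p = 0.00452; adjusted p = 0.409 with an estimated correlation). Of 23 presomitic and somite genes 2 fell, Meox2 by 1.51 ± 0.22 (adjusted p = 0.00738) and Cdx1 by 0.81 ± 0.16 (adjusted p = 0.0371). Adjusted over the list alone, 3 fell. The list shifted down (mean -0.47, camera adjusted p = 0.000248; adjusted p = 0.409 with an estimated correlation).

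Neuronal genes were lower in homozygotes as a list at the preset correlation. Of 39 measured neurogenesis genes 5 fell, 35 had a negative log2 fold change, and adjusted over the list alone 15 fell. Pou4f1 and Isl1, transcription factors of early sensory and motor neurons, fell by 0.85 ± 0.15 (adjusted p = 0.0172) and by 0.80 ± 0.15 (adjusted p = 0.0306). Neurod4, another neurogenic factor, was at least 2.14-fold lower (adjusted p = 0.0466), and with normexp its log2 fold change was -0.78 (adjusted p = 0.332). The list had a mean log2 fold change of -0.65 (camera adjusted p = 1.41e-10; adjusted p = 0.409 with an estimated correlation). The anterior and middle Hox genes shifted down (mean -0.55, camera adjusted p = 1.12e-07; adjusted p = 0.409 with an estimated correlation), with 22 of 23 members lower in value and none past the threshold alone. Hoxd1 had a log2 fold change of -1.29 ± 0.32 (adjusted p = 0.0764) and Hoxb4 of -0.61 ± 0.16 (adjusted p = 0.086). Hypoxia and glycolysis genes shifted up (mean 0.45, camera adjusted p = 1.16e-06; adjusted p = 0.609 with an estimated correlation), with 28 of 30 higher in value and none past the threshold. Pdk1 had a log2 fold change of 0.79 ± 0.21 (adjusted p = 0.098) and Pfkl of 0.78 ± 0.21 (adjusted p = 0.106). In all, 6 of 28 lists shifted at the preset correlation and 0 with an estimated one, and 5 other lists had a median, mean and test that differed in sign. With fry, the pharyngeal arch list passed (adjusted p = 0.00779) and no other list did, neurogenesis coming next (adjusted p = 0.0688). Within slides 1, 2 and 3 the mean log2 fold change was -1.28, -0.50 and -0.57 for neurogenesis, -0.94, -0.35 and -0.59 for anterior and middle Hox genes, and 0.37, 0.39 and 0.55 for hypoxia and glycolysis. It was -0.56, -0.40 and -0.43 for pharyngeal arch genes, -0.69, -0.29 and -0.53 for presomitic and somite genes, and -0.55, -0.37 and -0.69 for skeletal muscle, and with slide as a block each of these lists passed. The skeletal muscle list did not pass when probes had to be above background on all arrays (mean -0.16).

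**Figure D2:**
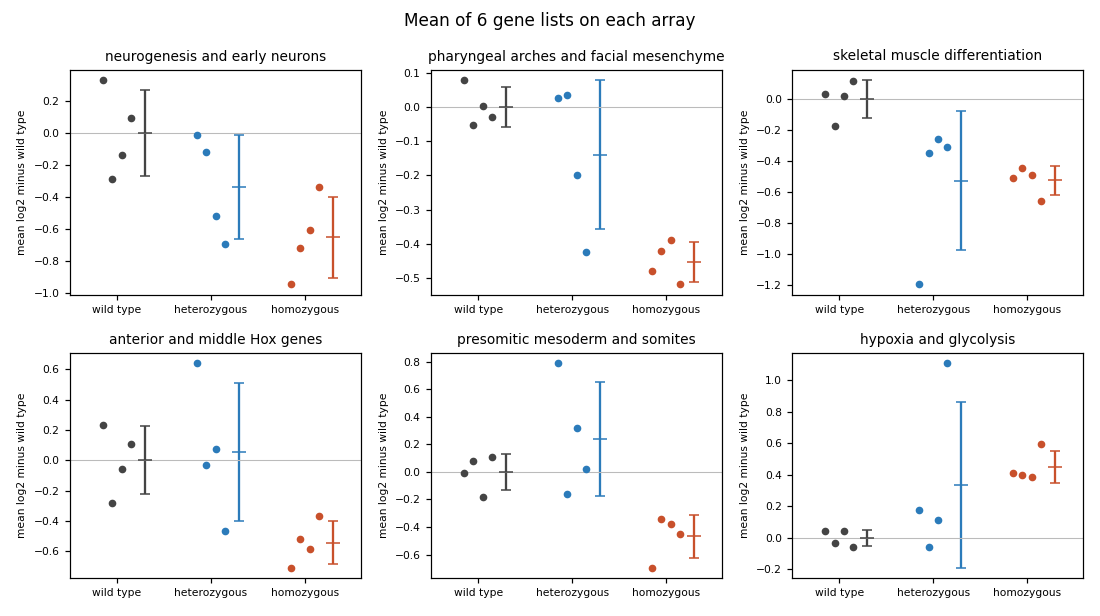
Mean of 6 gene lists on each array, as log2 signal minus the wild-type mean (vertical axes), with points for arrays and bars for the mean ± SD of 4 arrays per genotype. Homozygous arrays lie below wild type for the lists of the pharyngeal arches and presomitic mesoderm and above it for hypoxia and glycolysis, while heterozygous arrays spread widely.

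Genes with the largest increases in homozygotes included Rasl10a, higher by 1.73 ± 0.17 (adjusted p = 0.000646), Acsbg1, an acyl-CoA synthetase, by 1.60 ± 0.19 (adjusted p = 0.00167), Casp12 by 1.78 ± 0.32 (adjusted p = 0.0204), the desmosomal gene Pkp1 by 1.48 ± 0.27 (adjusted p = 0.0228) and Extl1 by 1.47 ± 0.30 (adjusted p = 0.0375). Tff1, Efcab6 and Mr1 were not well above background on the wild-type arrays and were at least 2.74-fold, 2.77-fold and 1.78-fold higher in homozygotes, where each was detected on 4 of 4 arrays. None of these 8 increases passed with normexp background correction, where the log2 fold changes were 0.15 for Rasl10a, 0.86 for Acsbg1, 0.29 for Casp12, 0.24 for Pkp1, 0.31 for Extl1, 0.10 for Tff1, 0.12 for Efcab6 and -0.10 for Mr1. The offset of normexp shrinks fold changes most for dim probes, so a lost call does not by itself show that a gene did not rise. Mrc1, a macrophage receptor, rose by 1.35 ± 0.29 (adjusted p = 0.0456), with wild-type replicate 2 apart from the other wild-type arrays. Among the largest decreases outside the lists were the cell adhesion genes Chl1 (-2.47 ± 0.31, adjusted p = 0.00259; -1.80 on a second probe) and Cdh7 (at least 1.91-fold lower, adjusted p = 0.000269). The transcripts ENSMUST00000001667 (-2.65 ± 0.13, adjusted p = 3.17e-06, the smallest of this comparison) and AK050844 (-2.62 ± 0.20, adjusted p = 9.71e-05) also fell. These transcripts have no symbol in the gene table and are named after their values were seen. Tecrl, a gene of heart and muscle, had a log2 fold change of -2.57 ± 0.44 (adjusted p = 0.0159), and Cox8b was at least 1.86-fold lower (adjusted p = 0.0097). With normexp Cdh7 (-0.63, adjusted p = 0.472) and Cox8b (-0.72, adjusted p = 0.401) did not pass. Perp, a target of p53, fell by 0.90 ± 0.11 (adjusted p = 0.00176), and Hhip, an inhibitor of Hedgehog signalling, by 0.75 ± 0.15 (adjusted p = 0.0342), with -0.48 on a second Hhip probe.

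Few single genes passed the threshold between heterozygous and wild-type embryos. Of 22563 genes 2 passed, both lower: the muscle gene Myot, at least 2.03-fold lower (adjusted p = 0.032), and the transcript ENSMUST00000001667, with a log2 fold change of -1.24 ± 0.13 (adjusted p = 0.0151) and named after its value was seen, since the gene table gives it no symbol. The bound for Myot is on the processed signal, and with normexp its log2 fold change was smaller, at -0.58 (adjusted p = 0.657). At an unadjusted p under 0.05 there were 3481 genes, where chance gives 1128, and the arrays did not overlap for 1504 genes, where chance gives 2.86%, so the low count of calls does not show that the other genes were alike. Neurogenesis genes had a mean log2 fold change of -0.34 (camera adjusted p = 4.23e-05), skeletal muscle genes of -0.53 (adjusted p = 0.00118), pharyngeal arch genes of -0.14 (adjusted p = 0.0296), and hypoxia and glycolysis genes of 0.34 (adjusted p = 0.00178), with no member past the threshold in any of them. With an estimated correlation these were adjusted p = 0.902, 0.883, 0.902 and 0.937. Pou4f1 had a log2 fold change of -0.49 ± 0.15 (adjusted p = 0.237), Lhx9 of -0.53 ± 0.19 (adjusted p = 0.262), Tnnc2 of -1.14 ± 0.24 (adjusted p = 0.232), Alx1 of -0.96 ± 0.21 (adjusted p = 0.232) and Ndrg1 of 0.73 ± 0.29 (adjusted p = 0.288).

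The heart list was lower in heterozygotes, and its mean rested on 1 array. Its mean log2 fold change was -0.73 (camera adjusted p = 0.00133; adjusted p = 0.937 with an estimated correlation), and its score against wild type was -3.08 on heterozygous replicate 1 and between -0.15 and 0.22 on the other 3. Without that replicate the mean was 0.05 and the list did not pass. The hypoxia score was 1.11 on heterozygous replicate 4, without which that list did not pass either (mean 0.08). The skeletal muscle score was -1.20 on heterozygous replicate 1, and without it the mean was -0.30 (adjusted p = 0.0491). The neurogenesis score was -0.01, -0.12, -0.52 and -0.70 on heterozygous replicates 1 to 4, and without replicate 4 the mean was -0.22 (adjusted p = 0.000549). Within slides 1, 2 and 3 the mean log2 fold change was -0.40, -0.30 and -0.79 for neurogenesis, -0.80, -0.18 and -0.43 for skeletal muscle, -0.05, -0.17 and -0.40 for pharyngeal arch genes, 0.02, 0.11 and 1.17 for hypoxia and glycolysis, and -1.38, 0.04 and 0.21 for heart genes, and with slide as a block the heart list did not pass. The pharyngeal list did not pass without wild-type replicate 2 (-0.16) or heterozygous replicates 3 (-0.12) or 4 (-0.05). In all, 5 of 28 lists shifted at the preset correlation and 0 with an estimated one, and 10 others had a median, mean and test that differed in sign. With fry no list passed (smallest adjusted p = 0.745). The number of genes called was 5 with slide as a block and 2 with array position as a block, and with position none of them was among the 2. Myot passed with 3 of the 12 arrays left out in turn. It lost its call with normexp, slide, position or title number as a fixed block, trend and robust variance and a fit of only the 2 genotypes. The count was 1 without wild-type replicate 1 or homozygous replicate 4. It was 0 with title number as a fixed block and without heterozygous replicate 3 or wild-type replicates 2, 3 or 4.

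**Figure D3:**
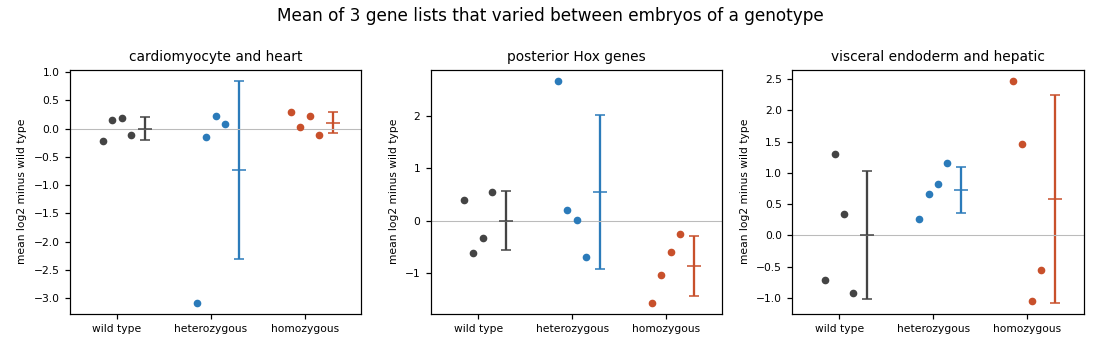
Mean of 3 gene lists on each array, as log2 signal minus the wild-type mean (vertical axes), with points for arrays and bars for the mean ± SD of 4 arrays per genotype. Heterozygous replicate 1 lies at -3.08 for the heart list and 2.66 for the posterior Hox genes, and the visceral endoderm and hepatic list spreads widely within wild type and homozygotes.

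Between homozygous and heterozygous embryos, 3 genes passed, all lower in homozygotes. Vit, a matrix protein, fell by 1.30 ± 0.14 (adjusted p = 0.00891), and the others, named after their values were seen, were the transcripts ENSMUST00000001667 (-1.42 ± 0.13, adjusted p = 0.00353) and AK050844 (-1.56 ± 0.20, adjusted p = 0.0327), to which the gene table gives no symbol. At an unadjusted p under 0.05 there were 1353 genes, where chance gives 1128, and the arrays did not overlap for 673 of 22563 genes, where chance gives 2.86%. Patterning genes of the trunk were lower in homozygotes: presomitic and somite genes had a mean log2 fold change of -0.71 (camera adjusted p = 6.54e-10; adjusted p = 0.13 with an estimated correlation), with 9 lower when adjusted over the list alone, and anterior and middle Hox genes of -0.60 (camera adjusted p = 6.25e-13; adjusted p = 0.233 with an estimated correlation), with 23 of 23 lower in value. Meox2 had a log2 fold change of -0.85 ± 0.22 (adjusted p = 0.477) and Hoxd3 of -0.64 ± 0.14 (adjusted p = 0.281). Pharyngeal arch genes (mean -0.31, adjusted p = 0.000189) and neurogenesis genes (mean -0.31, adjusted p = 0.000242) were also lower, with adjusted p = 0.216 and 0.502 with an estimated correlation. Posterior Hox genes (mean -1.40, adjusted p = 0.000443) and heart genes (mean 0.83, adjusted p = 5.39e-09) shifted too, and among the heterozygous arrays replicate 1 had the lowest heart score, -3.08, and the highest posterior Hox score, 2.66. Their estimated-correlation tests gave adjusted p = 0.444 and 0.502. Erythroid genes (mean -0.35, adjusted p = 0.00967), hypoxia and glycolysis genes (mean 0.11, adjusted p = 0.00967) and genes of CHARGE syndrome and hypogonadotropic hypogonadism (mean -0.24, adjusted p = 0.0235) completed the 9 of 28 lists that shifted, with adjusted p = 0.845, 0.877 and 0.332 with an estimated correlation. In 8 other lists the median, mean and test differed in sign. With fry, the pharyngeal arch, presomitic and somite, and retinoic acid lists passed, each with adjusted p = 0.0429. The retinoic acid list did not pass with camera (adjusted p = 0.0625).

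Within slides 1, 2 and 3 the homozygous minus heterozygous mean was -1.01, -0.66 and -0.41 for presomitic and somite genes, -1.01, -0.59 and -0.01 for anterior and middle Hox genes, -0.51, -0.22 and -0.03 for pharyngeal arch genes, and -0.88, -0.20 and 0.22 for neurogenesis. It was -3.00, -1.05 and 0.28 for posterior Hox genes and 1.90, -0.20 and -0.04 for heart genes, and with slide as a block the hypoxia and CHARGE lists did not pass. Without heterozygous replicate 1 the heart (0.05), erythroid (-0.31), hypoxia (0.06) and CHARGE (-0.18) lists did not pass, the means of the posterior Hox (-0.70, adjusted p = 0.0478) and neurogenesis (-0.21, adjusted p = 0.0485) lists were smaller, and 6 genes were called. The erythroid list also did not pass without heterozygous replicate 2 (-0.22) or homozygous replicates 1 (-0.23) or 2 (-0.14), and had a mean of -0.59 without homozygous replicate 3. The hypoxia list did not pass without heterozygous replicates 2 (-0.02) or 3 (0.04) or homozygous replicate 4 (0.06), and had a mean of 0.37 without heterozygous replicate 4. The CHARGE list did not pass without heterozygous replicate 2 (-0.24) or homozygous replicate 4 (-0.18). The count of genes was 1 without homozygous replicate 1 or heterozygous replicates 2 or 3, where Vit lost its call. It was 2 with quantile normalization, where Vit also lost its call, and 4 with slide as a block. It was 0 with array position or title number as a fixed block, with normexp or in a fit of only the 2 genotypes.

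Genes called in homozygotes lay between the other genotypes in heterozygotes. The median heterozygous log2 fold change of the 305 genes, signed by the homozygous direction, was 0.44, against 0.92 in homozygotes, and 301 had the homozygous direction. The 4 heterozygous arrays gave 0.46 ± 0.12 (SD) against the wild-type mean. Unchanged groups simulated against the same shared controls gave 0.24 (0.22 to 0.27 in 100 simulations) and 91.1% with the same sign. Genes were simulated independently of each other, so this range leaves out variation that genes share and is too narrow. With the wild-type arrays split so that the comparisons shared no array, the 6 splits gave 0.37 to 0.88 over 24 to 153 called genes. With array position as a block the 305 genes gave 0.36, and within slides 1, 2 and 3 they gave 0.43, 0.43 and 0.66. The value with position as a block rests on the 1 wild-type array off position 1. Intermediate heterozygous values and an effect of position 1 therefore cannot be told apart. The covariance of the fold changes over all genes was 0.0674, against 0.0262 simulated, and 0.029 to 0.0535 in the splits.

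Called genes were not detectably enriched near the mutated locus. Within 20 Mb of Chd7 on chromosome 4, 2 of 69 tested genes were called, against 1.73% elsewhere (odds ratio 1.70, p = 0.337, two-sided Fisher's exact test). With windows of 10 and 50 Mb the odds ratios were 1.26 and 0.47 (p = 0.554 and 0.449, the same exact test). For changed genes near Chd7, 3 of 27 alternatives gave an unadjusted p under 0.05 in this exact test: normexp background correction (odds ratio 6.18, p = 0.0452), array weights (3.69, p = 0.00453) and leaving out wild-type replicate 2 (5.44, p = 0.00792).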

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

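The tests of array position and of the heart genes were chosen after the results were seen, and the other tests were set before. Single arrays stood apart from the other 3 of their genotype in 4 of 84 list scores and 12 of 157 gene levels, where chance gives about 4.2 and 7.85.

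Heart genes were low on heterozygous replicate 1, where the heart list score was -3.08 and the skeletal muscle score -1.20, each far below the other heterozygous arrays. The log2 signal of Pln, a regulator of the cardiac calcium pump, was -8.67 there and that of Tecrl -5.21, but neither gene marks this embryo alone: against wild type (-4.88 to -4.19 and -1.83 to -1.43) both were also lower on the other heterozygous arrays (-5.88 to -5.54 and -2.87 to -2.79) and on the homozygous arrays (-7.21 to -6.60 and -4.38 to -4.08). For the list score, and not for Pln and Tecrl, the tables argue against an effect of the genotype that all heterozygotes share. The other 3 heterozygous arrays had a median heart score of 0.0887. An effect in only some heterozygous embryos stays open, since the array was picked for standing apart from these 3. Heart tissue missing from the RNA of this embryo and another cause in the same embryo cannot be told apart: 90.0% of the 30 measured heart genes were lower there than on the other 11 arrays, but these are the genes of the score itself, so this describes the pattern and does not test its cause. The same array stood apart upwards in Dll3 (1.14), Hoxd1 (-1.54) and Hoxa9 (-1.90), which was not tested.

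Array position 1 held only wild-type arrays, so it predicts no difference between homozygous and heterozygous arrays. In genes called on 2 homozygous arrays, the other 2 differed from heterozygotes by 0.451 to 0.547 of their difference from wild type in 6 splits. For genes called between homozygous and wild-type embryos this argues against position 1 as the whole. It does not cover the other positions, since position 3 held homozygous replicates 1 and 3, wild-type replicate 3 and no heterozygous array. Over all tested genes the counts had a pattern that position would also give. An unadjusted p under 0.05 was found for 3828 genes in homozygotes and 3481 in heterozygotes against wild type. Between homozygotes and heterozygotes there were 1353, where chance gives 1128. The arrays did not overlap for 3176, 1504 and 673 genes in these comparisons, where chance gives 2.86%. With position as a block the 305 genes kept a median of 0.90 of their log2 fold change, but its median SE rose from 0.151 to 0.266, and 20 genes were called, 6 of them among the 305. This share rests on the 1 wild-type array off position 1, so it decides nothing about position. A stage difference that the Hox genes follow could not be decided. With the Hox score as a covariate over 11 arrays, without heterozygous replicate 1, the genes kept a median share of 0.862 (0.776 to 0.887 with an array left out). Calls fell from 286 to 15 as the median SE rose from 0.149 to 0.233. The score did not overlap between homozygous (-0.544 to -0.205) and wild-type arrays (-0.119 to 0.398). The genes were also called for a small spread within genotypes, which favours a high share kept. A part played by position, and a stage difference, stay open.

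The intermediate heterozygous values and array position 1 cannot be told apart, because only 1 wild-type array lay off that position. On 243 genes called without it, this array lay 0.223 from the other wild-type arrays in the homozygous direction, against 0.49 for heterozygotes and 1.01 for homozygotes. A split of the heterozygous and wild-type arrays that put the 3 wild-type arrays of position 1 with heterozygous replicate 2 called 266 genes, where the real split called 2. Their median absolute log2 fold change was 0.54, 17 changed at least 2-fold, and 8 were among the 305. This split was picked for having the most calls, and whether it reflects a structure of the samples was not tested. The same 3 arrays with heterozygous replicate 1, 3 or 4 gave 0 genes each, so the 266 calls were not shown to follow position. With position as a block 2 genes were called between the real groups, neither of them among the 2 called without it.

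As many as the 305 genes came from 1 of the 35 splits of the 8 arrays, the real one, and the highest other gave 40. For the 132 changed at least 2-fold it was also 1 of 35, with a highest other of 39. This argues against a random grouping of the arrays, but 1 of 35 is the lowest share these splits can give. The splits take no account of slide, position or title number, so a structure of the samples is not excluded. With position as a block 20 genes were called, and with title number as a fixed block 19. For the 3 genes between homozygotes and heterozygotes it was 1 of 35 in both counts, with a highest other of 1. Counts this small do not exclude chance. In this comparison 1353 genes had an unadjusted p under 0.05, where chance gives 1128. The arrays did not overlap for 673 of 22563 genes, where chance gives 2.86%. With position or title number as a fixed block, with normexp or in a fit of only the 2 genotypes, 0 genes were called. Chance cannot be excluded for the 2 genes between heterozygotes and wild type either. There, 2 of 35 splits gave as many in both counts, with a highest other of 266, or 17 at least 2-fold. Nor can chance be excluded for counts of shifted lists. As many as the 6 lists of homozygotes against wild type came from 14 of 35 splits (highest other 10), as many as the 5 of heterozygotes against wild type from 28 (highest other 12), and as many as the 9 of homozygotes against heterozygotes from 13 (highest other 13).

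Other single arrays stood apart as follows. Wild-type replicate 2 had log2 signals of -3.92 for Mrc1 and 1.48 for Hk1. Heterozygous replicate 2 had -1.49 for Alx1 and a semaphorin list score of -0.0259. Heterozygous replicate 3 had 3.03 for Dusp6 and heterozygous replicate 4 had 0.878 for Hoxb4. Homozygous replicate 4 had a hypoxia and glycolysis score of 0.599, homozygous replicate 2 a Bmp10 signal of -4.23 and homozygous replicate 1 a Tbx5 signal of 0.203. Ddx3y, outside the comparisons, was above background on wild-type replicate 1 alone, at -6.18, where the other Y-linked genes were not.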

How the results depend on the processing

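Array position as a block was added after seeing the data, and every other alternative was fixed before. Where a value below crossed a threshold, moved or turned, the cause was not tested. The value table held the same intensities and gave 310, 2 and 3 genes for homozygous against wild type, heterozygous against wild type and homozygous against heterozygous, the order used below, with its 75th percentile taken over probes. Across all alternatives, values of named genes stayed on the same side of the threshold 1563 times, lost it 210 times, passed it newly 10 times and turned direction 1 time, and list tests did so 1992, 55, 47 and 6 times. A change of sign between 2 values that both missed the threshold was counted as staying.

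Normexp background correction gave 91, 1 and 0 genes (47, 1 and 0 at least 2-fold), with 9.89% of the 91 higher against 36.1% before, an odds ratio for changed genes near Chd7 of 6.18 (array weights 3.69), and turned Mr1 to -0.10. No filter on dim probes, which tested more genes, gave 188 and 5 genes (5 at least 2-fold) in the first pair of comparisons. Requiring probes above background on all arrays gave 1 gene (1 at least 2-fold) for heterozygotes, as did trend and robust variance (1 and 1) and a fit of only the 2 genotypes compared (1 and 1, and 0 and 0 between homozygotes and heterozygotes). Slide as a block gave 5 genes for heterozygotes, 4 at least 2-fold. Array weights gave 544 genes for homozygotes against wild type and 7 against heterozygotes. With an estimated inter-gene correlation 0, 0 and 0 lists shifted. With the wild-type arrays split 2 and 2 the median heterozygous change was 0.58, the median of 6 splits.

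Array position as a block gave 20 genes (20 at least 2-fold) for homozygotes against wild type and 0 (0 at least 2-fold) against heterozygotes, 11 lists and 8 lists for homozygotes and heterozygotes against wild type, and a median heterozygous change of the genes changed in homozygotes of 2.30 over its own 20 genes. The list test turned from down to up, past the threshold, for neural tube patterning (mean 0.47 in homozygotes, 0.32 in heterozygotes), erythroid (0.87 in homozygotes) and endothelial genes (0.21 in heterozygotes), all against wild type.

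The number before the point in the sample titles is shared across genotypes. The 11 pairs of arrays with the same number had a median correlation across genes of 0.0231 (-0.317 to 0.294), 4 of them over 0.1. The 37 other pairs had a median of 0.0196, 9 of them over 0.1. Of the 10 arrays with a partner, 5 correlated best with an array of their own number and 5 did not. The share that chance would give was not computed, so a pairing by number is neither shown nor excluded. Slide and number overlap. With this number as a fixed replicate block 19, 0 and 0 genes were called (19, 0 and 0 at least 2-fold), 33 of the 38 named genes lost their call, the heterozygous change was 0.88, and the visceral endoderm list test turned from up to down between homozygotes and heterozygotes (mean -0.86, against -0.14 before). As a random replicate block it gave 295, 2 and 3 genes.

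Leaving out each array in turn gave 112 to 447, 0 to 3 and 1 to 6 genes, 71 to 156 genes changed at least 2-fold, homozygous minus wild type, with 0 to 3 and 1 to 6 in the others, and 6 to 8, 3 to 6 and 5 to 12 lists. The heterozygous change ranged from 0.36 to 0.57 and the odds ratio for changed genes near Chd7 from 1.18 to 5.44. For the visceral endoderm list between homozygotes and heterozygotes, the test turned from up to down without homozygous replicate 1 (mean -0.77) and passed upwards without homozygous replicates 3 (0.40) or 4 (0.24). Signal over background limits what can be read from dim genes. Of the 38 named genes past the threshold, 17 lost it with normexp, whose offset shrinks the fold changes of dim probes, and 8 with no filter.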

Other observations

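The lists described here were fixed before the data were examined and were chosen for description after their values were seen. Tissue lists varied between embryos of the same genotype. The visceral endoderm and hepatic list, which holds genes of the yolk sac and liver bud, had scores against the wild-type mean of 2.47, 1.46, -1.05 and -0.55 in the homozygous embryos, of 0.26, 0.66, 0.82 and 1.15 in the heterozygous ones and of -0.71, 1.30, 0.34 and -0.92 in wild type. Its mean log2 fold change was 0.58 in homozygotes against wild type (camera adjusted p = 0.0594; adjusted p = 0.8 with an estimated correlation), with 24 of 24 members higher in value and none past the threshold. The list passed in 6 of 25 alternatives, with normexp (mean 0.48), quantile normalization (0.57), slide as a block (0.97) and without homozygous replicates 3 (1.13) or 4 (0.96) or wild-type replicate 2 (1.02), and its mean was -0.05 without homozygous replicate 1. Within slides 1, 2 and 3 the mean was 3.18, 0.64 and 0.12. Erythroid scores ran from -0.88 to 0.53 within wild type and from -0.81 to 0.52 within homozygotes, and in homozygotes against wild type that list passed downwards with slide as a block (-0.39) and without homozygous replicate 3 (-0.43) or wild-type replicate 3 (-0.49), and upwards with array position as a block (0.87).

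Lists of cell cycle, ribosome biogenesis and p53 target genes did not pass the threshold between homozygotes and wild type over all arrays. Cell cycle genes had a mean log2 fold change of -0.05 (camera adjusted p = 0.23), ribosome biogenesis genes of -0.02 (adjusted p = 0.47) and p53 targets of -0.07 (adjusted p = 0.239), where 1 of 29 measured targets passed, Perp, which was lower. The cell cycle list passed downwards with title number as a fixed block (-0.08). Endothelial genes (-0.08, adjusted p = 0.165) and trophoblast and decidua genes (0.11, adjusted p = 0.763) did not pass either. The endothelial list passed without homozygous replicate 1 (-0.17) or wild-type replicate 4 (-0.13), and with title number as a fixed block (-0.15). The other CHD remodellers had a mean of -0.05 over 9 genes (adjusted p = 0.527), and none of them passed.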
